A study of Homo sapiens with 24 samples.

How the data were processed

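The deposited table held a whole-number count per gene and library for 58302 Ensembl genes and 24 libraries, and these counts were used directly. Per the submitters' processing notes, reads were aligned with GSNAP (version not given) to the human genome build GRCh38. The counting tool, the annotation, the strand setting and any removal of mouse reads are not given in the sources used here. Per the labels' protocols, RNA came from flash-frozen tumours, and libraries were made with TruSeq RNA v2 or TruSeq Stranded Total RNA kits, without a statement of the kit for each library, so that a kit effect could not be examined. Each library came from 1 animal, as the labels give a separate animal for each. Gene symbols and positions came from GENCODE v29 on GRCh38, and 57532 genes were matched to a symbol.

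Genes were kept by the filterByExpr function of edgeR on the 6 groups, which left 24291 genes tested. Library sizes were scaled by the trimmed mean of M values (TMM). A negative binomial model with 1 coefficient per group was fitted to all 24 libraries (18 residual degrees of freedom) with edgeR 4.0.16 in R 4.3.3, and contrasts were tested with the robust quasi-likelihood F-test, which is two-sided. P values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The contrasts were each dose against vehicle and 80 against 1 mg/kg within each model, the difference of each dose effect between models, and vehicle between models. The words rose, fell, higher, lower and changed refer to genes past that threshold, and values after the word differed may not pass it. CPM values used the TMM factors. Principal components were computed from log2 CPM with a prior count of 2.

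A fixed set of 23 gene lists was tested. They covered estrogen receptor-induced and estrogen receptor-repressed targets, DNA replication and G1/S, mitosis and G2/M, cyclins with their kinases and inhibitors, luminal, basal, growth factor receptors, the BCL2 family, cholesterol synthesis, interferon-stimulated genes, antigen presentation, the unfolded protein response, hypoxia, ribosome biogenesis, p53 targets, immediate early genes, mitochondrially encoded genes, histones, and fibroblast, endothelial, leukocyte and adipocyte markers. Of the 28 histone genes 27 were matched and 19 tested, and 15 of 16 endothelial, 13 of 16 leukocyte and 8 of 9 adipocyte markers were tested, while the other lists were tested in full. Lists share members, 4 of the estrogen-induced, 3 of the repressed, 5 of the growth factor receptor and 4 of the p53 list being also in another list. In a xenograft the stromal markers can come from mouse cells, whose reads may align in part to human genes, and tumour cells also express some of these markers, so that the stromal lists do not measure a cell type by themselves.

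Each list was tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 23 lists of a comparison. As alternatives, camera with an estimated correlation and fry were run. With an estimated correlation, 4 of 8 camera calls held at 80 mg/kg and 2 of 14 at 1 mg/kg against vehicle in HCI-011, and 4 of 11 between the doses. In HCI-003 these were 3 of 11, 4 of 12 and 0 of 3. For the effects between models they were 0 of 10 at 80 mg/kg and 2 of 14 at 1 mg/kg, and 0 of 5 for vehicle. Counts of members given as adjusted over the list alone used a Benjamini-Hochberg adjustment within the list. The list score of a library was the mean log2 CPM (prior count 2) over the tested members, and the score difference is given with its SE. An exact two-sided permutation test of 4 against 4 libraries has 70 splits and a smallest p of 0.0286. After Benjamini-Hochberg adjustment over 23 lists, its value can fall below 0.05 only where many lists reach that smallest p. It was 0.0730 after adjustment for estrogen-induced targets at 80 mg/kg in HCI-011.

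Before the data were examined, the tests, the gene lists, the alternatives and the rule for named genes were fixed. The rule always named ESR1, PGR, GREB1, TFF1, MYC, CCND1, CCND2, MKI67, ERBB2, CDKN1A, FOXA1 and GATA3, and 1 more gene that is not reported here. For a dose against vehicle it named up to 10 genes each way with the largest log2 fold change among those past the threshold with a mean of at least 2 CPM over the 8 libraries and all 4 treated libraries beyond all 4 vehicle libraries. For the other comparisons it named up to 5 each way, for effects between models without the condition on overlap and with the mean over 16 libraries. For each list it named up to 4 members with the smallest p. The text describes part of the genes so named, and members of the target lists that moved against the name of their list (FKBP4, ABCA3, DDIT4 and EGLN3) were added after their values were seen.

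Alternatives for every count of genes were DESeq2 size factors and upper-quartile factors in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter on low counts, a filter of 1 CPM in 12 libraries, a test against a 1.5-fold change (glmTreat), a host stroma score as a covariate, fits of the 12 libraries of a model or the 8 of a comparison, and each library left out in turn. The host stroma score was the mean log2 CPM over the fibroblast, endothelial and leukocyte lists, centred within each model. Fits without HCI-011 1 mg/kg replicate 2 and 80 mg/kg replicate 2, and without HCI-003 1 mg/kg replicate 1 and 80 mg/kg replicate 2, which lay farthest out on components 2 and 3 of each model, were chosen after the data were seen. Every split of the 8 libraries of a comparison into 4 and 4 was also tested (35 splits, or 40 drawn for the effects between models). Overlaps of calls were set against the product of the 2 counts divided by the number of genes tested, 10 simulations of unchanged groups against shared vehicles, and 6 splits of the vehicle libraries between the doses.

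The procedure was tested on simulated data with the depth of these libraries and 23683 genes, of which 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. The changed genes were drawn only from genes above a minimum mean count. Each gene had 1 spread for both models, so that the larger spread between HCI-003 libraries was not simulated. The rates therefore do not cover genes with low counts and may be too high for HCI-003. The changed genes were also a far smaller share than the 32.1% and 20.0% of genes called at 80 mg/kg in HCI-011 and HCI-003. With fewer changed genes the Benjamini-Hochberg adjustment is stricter, which can make the rates too low for those comparisons. For 80 mg/kg against vehicle in HCI-011, 55.2%, 74.6% and 95.5% of them were called, with 9 false calls. Between the doses in HCI-003, 53.7%, 83.6% and 98.5% were called, with 6 false calls. In HCI-003, 47.8%, 82.1% and 97.0% were called for 80 mg/kg against vehicle with 10 false calls, and a comparison simulated without change had 0 calls. In HCI-011 52.2%, 76.1% and 93.9% were called between the doses, with 5 false calls. That test was run after the measured data had been fitted.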

Results

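RNA sequencing libraries were collected from tumours of 2 patient-derived xenograft models of estrogen receptor-positive breast cancer, HCI-011 and HCI-003. Such a model is a human tumour propagated in mice, so that a sample holds human tumour cells together with mouse stroma. The tumours grew in immunocompromised mice that received estrogen, and treatment began at a tumour volume of 450 to 850 mm3. Mice received vehicle, 1 mg/kg or 80 mg/kg of giredestrant (GDC-9545), an oral antagonist and degrader of the estrogen receptor, once daily for 5 days, and tumours were taken 4 h after the last dose. The 6 groups held 4 libraries each, 24 in total, from separate animals, and all libraries of a model came from the same tumour line, so that the spread between libraries is a spread between animals and not between patients. Total counts ran from 26.7 to 40.8 M per library (M, counts in units of 1e+06). In HCI-011 the mean total was 33.0 ± 0.480 M for vehicle, 29.4 ± 1.85 M for 1 mg/kg and 30.8 ± 3.23 M for 80 mg/kg (SD, n = 4). In HCI-003 it was 33.0 ± 2.31, 33.9 ± 2.76 and 36.7 ± 3.90 M in the same order. Expression is given in counts per M (CPM) as mean ± SD over 4 libraries. Effects are given as log2 fold changes ± SE with 4 libraries per group, and adjusted p values are two-sided values of the edgeR quasi-likelihood test after Benjamini-Hochberg correction.

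On both models together, the first principal component held 75.9% of the variance and parted HCI-011 from HCI-003. Within each model the first component parted vehicle from treated libraries, with 39.7% of the variance in HCI-011 and 27% in HCI-003. In HCI-011, 1 mg/kg replicate 2 lay apart on the second component (16.6% of the variance), at -72.3, and 80 mg/kg replicate 2 on component 3 (9.63%), at -56.5, and both had high scores for host stroma markers (0.558 and 0.579 above the model mean, log2). In HCI-003, 1 mg/kg replicate 1 lay farthest out on component 2 (18.8%), at 60.7. On component 3 (13.5%) 80 mg/kg replicate 2 lay farthest out, at -50.7, with 1 mg/kg replicate 1 at 49.3. Mitochondrially encoded genes took 5.19 ± 0.397% of the counts in HCI-011 vehicle, 6.37 ± 0.577% at 1 mg/kg and 5.77 ± 0.427% at 80 mg/kg. In HCI-003 their share was 3.55 ± 0.575%, 2.56 ± 0.380% and 2.83 ± 0.386%. The 10 most abundant genes took between 4.09% and 6.69% of the counts on average per group. Replicates differed by far more than counting noise, with a lowest chi-square per degree of freedom of 5.53 over all pairs within groups. It ran from 5.53 to 34.3 in HCI-011 and from 18.1 to 81.3 in HCI-003, while the tests used 1 estimate of spread per gene for both models. Positions on GRCh38 (GENCODE v29) of genes that recur in every comparison were as follows. ESR1 was ENSG00000091831, chromosome 6, 151656691 to 152129619. PGR was ENSG00000082175, chromosome 11, 101029624 to 101130524. GREB1 was ENSG00000196208, chromosome 2, 11482341 to 11642788. TFF1 was ENSG00000160182, chromosome 21, 42362282 to 42366594. MYC was ENSG00000136997, chromosome 8, 127735434 to 127741434. MKI67 was ENSG00000148773, chromosome 10, 128096659 to 128126385. CDKN1A was ENSG00000124762, chromosome 6, 36676460 to 36687339. PDZK1 was ENSG00000174827, chromosome 1, 145670852 to 145708148.

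The first comparison asked what the high dose changed in HCI-011 tumours. Genes of the estrogen response and of cell division fell at 80 mg/kg, while the gene of the drug target itself rose. PGR, the progesterone receptor and a classical estrogen target, fell from 195 ± 54.5 to 17.9 ± 1.78 CPM (-3.44 ± 0.36, adjusted p = 5.50e-07). MYC, a growth-promoting transcription factor, fell from 70.4 ± 25.0 to 3.56 ± 1.00 CPM (-4.30 ± 0.31, adjusted p = 6.07e-09). ESR1, which encodes the estrogen receptor alpha, rose from 800 ± 57.2 to 2121 ± 153 CPM (1.41 ± 0.24, adjusted p = 0.000116). In all, 7789 of 24291 genes tested changed, 3700 higher and 4089 lower, of which 958 rose and 1195 fell at least 2-fold. With upper-quartile scaling the larger part was higher, 4448 against 3650 lower, as with limma-voom (5498 and 5430).

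Of 51 estrogen receptor-induced targets, 43 fell and 2 rose, and the mean log2 CPM over the list differed by -1.68 ± 0.06 (camera adjusted p = 2.46e-36). GREB1, a receptor cofactor, fell by 0.98 ± 0.20, and the trefoil factor TFF1 by 2.24 ± 0.35. NOS1AP changed by -2.39 ± 0.16 and SUSD3 by -2.76 ± 0.20. The members that rose were the co-chaperone FKBP4 (0.31 ± 0.11) and the lipid transporter ABCA3 (0.66 ± 0.16). Of 20 estrogen-repressed targets, 16 rose and 2 fell (score difference 1.16 ± 0.08, camera adjusted p = 1.66e-12), among them BLNK at 1.66 ± 0.14, TP53INP2 at 2.07 ± 0.16 and ERBB2, the HER2 receptor gene, at 0.75 ± 0.10. The members that fell, DDIT4 (-1.51 ± 0.36) and EGLN3 (-1.70 ± 0.55), are also known to respond to low oxygen. Genes of DNA replication and the G1/S step fell in 30 of 31 cases (31 when adjusted over the list alone; camera adjusted p = 1.31e-27), with RFC3 at -1.21 ± 0.10 and MCM3 at -0.87 ± 0.08. All 28 genes of mitosis and G2/M fell (score difference -1.20 ± 0.09, camera adjusted p = 4.37e-43), with AURKA at -1.21 ± 0.10, CCNB1 at -1.34 ± 0.12 while MKI67, the gene of a proliferation antigen, fell by 1.00 ± 0.13.

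Hypoxia genes fell in 14 of 15 cases (15 when adjusted over the list alone), with the glucose transporter SLC2A1 at -1.97 ± 0.29. The list score differed by -1.55 ± 0.39 (camera adjusted p = 5.31e-07; adjusted p = 0.367 with an estimated correlation). One library, 80 mg/kg replicate 3, had a hypoxia score of 7.39 where the other 3 lay between 5.92 and 5.96. Of 24 genes of cholesterol synthesis, 18 fell (20 when adjusted over the list alone), with ACAT2 at -1.40 ± 0.13 and EBP at -1.11 ± 0.11 (camera adjusted p = 7.04e-10; adjusted p = 0.186 with an estimated correlation). Of 20 genes of ribosome biogenesis, 16 fell (17 when adjusted over the list alone), with the methyltransferase FBL at -0.85 ± 0.09 and the nucleolar protein NPM1 at -0.80 ± 0.09 (camera adjusted p = 7.04e-10; adjusted p = 0.0685 with an estimated correlation). Of 18 genes of the unfolded protein response, 10 fell and 1 rose (camera adjusted p = 0.00357; adjusted p = 0.367 with an estimated correlation). With an estimated correlation, the calls for the induced targets (adjusted p = 9.51e-06), the repressed targets (9.51e-06), G1/S (0.0424) and mitosis (0.0205) held.

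The other 15 lists did not pass camera. Luminal lineage genes moved both ways, with 9 higher and 6 lower of 20. The keratins KRT8 (-1.92 ± 0.21), KRT18 (-1.46 ± 0.17) and KRT19 (-1.64 ± 0.18) fell, while the lineage factor GATA3 (0.78 ± 0.09) rose. Growth factor receptors and adaptors had 4 members higher and 5 lower, among them INSR at 1.44 ± 0.13 and IRS1 at -1.77 ± 0.28. In the BCL2 family 4 rose and 3 fell, with the survival gene MCL1 at 0.75 ± 0.08 and the death agonist BID at -0.92 ± 0.10. Among p53 targets 5 rose and 3 fell, and the cell cycle inhibitor CDKN1A was at -1.25 ± 0.23. Rises and falls numbered 3 and 8 of 18 for cyclins, kinases and inhibitors, 2 and 2 of 16 for basal genes, 2 and 7 of 27 for interferon-stimulated genes and 2 and 3 of 13 for antigen presentation. They numbered 2 and 4 of 15 for immediate early genes, 1 and 0 of 13 for mitochondrially encoded genes and 3 and 0 of 19 for histones. For host cell markers they numbered 4 and 1 of 20 (fibroblast), 1 and 0 of 15 (endothelial), 0 and 0 of 13 (leukocyte) and 5 and 0 of 8 (adipocyte). The adipocyte score was 2.71 in 80 mg/kg replicate 2 and -0.18 to 0.55 in the other 3 libraries, and without that replicate PPARG, CIDEC and LPL no longer passed (adjusted p = 0.635, 0.702 and 0.740). Signs of the median change, the score difference and camera differed for basal genes (median 0.27, score -0.18 ± 0.33, camera lower), growth factor receptors (median -0.20, score -0.08 ± 0.12, camera higher) and p53 targets (median -0.04, score -0.06 ± 0.07, camera higher), and the endothelial median (0.05) and score (-0.00 ± 0.18) differed too.

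Among the largest changes, with all 4 treated libraries beyond all 4 vehicle libraries, NXPH1, a secreted neurexin ligand, rose by 4.84 ± 0.23, the scaffold gene IQGAP2 by 4.08 ± 0.33 and the iron reductase gene CYBRD1 by 3.99 ± 0.42. The interleukin-1 receptor IL1R1 rose by 3.88 ± 0.46, COLEC12 by 3.88 ± 0.35 and the zinc transporter SLC30A2 by 3.25 ± 0.35. The scaffold gene PDZK1 changed by -6.14 ± 0.31, the fatty acid elongase ELOVL2 by -6.04 ± 0.39, the noncoding RNA LINC01016 by -5.20 ± 0.52 and the potassium channel KCNH1 by -4.64 ± 0.36. SCNN1G, a sodium channel subunit, changed by -4.61 ± 0.45, RAMP1 by -4.49 ± 0.42 and the hormone gene TRH by -4.48 ± 0.33.

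The low dose in HCI-011 asked whether an 80-fold smaller amount still changed expression. At 1 mg/kg, 3058 genes changed, 1290 higher and 1768 lower, of which 329 rose and 336 fell at least 2-fold. PGR fell from 195 ± 54.5 to 30.7 ± 8.01 CPM (-2.66 ± 0.35, adjusted p = 9.04e-05) and MYC from 70.4 ± 25.0 to 20.4 ± 3.64 CPM (-1.79 ± 0.27). ESR1 rose to 1600 ± 195 CPM (1.00 ± 0.24, adjusted p = 0.00846). GREB1 (-0.42 ± 0.20, adjusted p = 0.182), TFF1 (-0.90 ± 0.34, adjusted p = 0.0886) and CDKN1A (-0.22 ± 0.23, adjusted p = 0.576) did not pass the test.

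Of the estrogen-induced targets 25 fell and 2 rose (33 and 5 when adjusted over the list alone; score difference -0.81 ± 0.06, camera adjusted p = 3.98e-18), with SUSD3 at -1.72 ± 0.19 and PDZK1 at -2.99 ± 0.26. Of the repressed targets 10 rose and 1 fell (camera adjusted p = 3.86e-08), with BLNK at 1.27 ± 0.14 and IL1R1 at 2.60 ± 0.45. These calls held with an estimated correlation (adjusted p = 0.000576 and 0.000400). Genes of mitosis fell in 26 of 28 cases (28 when adjusted over the list alone), with PLK1 at -0.83 ± 0.13 and AURKA at -0.60 ± 0.10 (camera adjusted p = 4.02e-25; adjusted p = 0.103 with an estimated correlation). G1/S genes fell in 14 of 31 cases (20 when adjusted over the list alone; camera adjusted p = 1.03e-12; adjusted p = 0.228 with an estimated correlation). Ribosome biogenesis genes fell in 13 of 20 cases (15 when adjusted over the list alone; camera adjusted p = 4.02e-09; adjusted p = 0.103 with an estimated correlation) and cholesterol genes in 9 of 24 (11 when adjusted over the list alone; camera adjusted p = 1.90e-06; adjusted p = 0.328 with an estimated correlation).

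Hypoxia genes fell in 6 of 15 cases at 1 mg/kg (14 when adjusted over the list alone; score difference -1.23 ± 0.45; camera adjusted p = 3.59e-09; adjusted p = 0.264 with an estimated correlation), with SLC2A1 at -1.23 ± 0.29. The score of 1 mg/kg replicate 2 was 5.36 where the other 3 lay between 6.82 and 7.17, and without it the difference was -0.81 ± 0.18, the camera call held and SLC2A1 was at -1.08 (adjusted p = 0.0314). Falls also numbered 7 in the unfolded protein response (camera adjusted p = 3.55e-06; adjusted p = 0.169 with an estimated correlation) and 6 among immediate early genes, with KLF6 at -0.72 ± 0.17 and IER3 at -1.03 ± 0.24 (camera adjusted p = 0.00320; adjusted p = 0.429 with an estimated correlation). Leukocyte markers were higher, with 5 of 13 rising (8 when adjusted over the list alone; camera adjusted p = 0.000628; adjusted p = 0.330 with an estimated correlation), and 1 mitochondrially encoded gene rose (camera adjusted p = 0.00154; adjusted p = 0.497 with an estimated correlation). Without 1 mg/kg replicate 2 the leukocyte genes AIF1 and PTPRC no longer passed (adjusted p = 0.116 and 0.155). Interferon-stimulated genes were called higher with 5 rising and 1 falling (camera adjusted p = 0.000862; adjusted p = 0.505 with an estimated correlation), and without 1 mg/kg replicate 2 that call ended (adjusted p = 0.0730). Antigen presentation (4 higher, camera adjusted p = 0.0378; adjusted p = 0.572 with an estimated correlation) and histones (1 higher, camera adjusted p = 0.0398; adjusted p = 0.505 with an estimated correlation) were called higher. The antigen presentation call ended without vehicle replicate 1 (0.0530) or 3 (0.0887) or 1 mg/kg replicate 1 (0.160) or 2 (0.320), and the histone call without vehicle replicate 2 (0.114) or 1 mg/kg replicates 1 (0.0840), 3 (0.119) or 4 (0.0520), each an adjusted p.

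At 1 mg/kg the genes with the largest rises included IQGAP2 (3.27 ± 0.32), NXPH1 (2.93 ± 0.22), SLC30A2 (2.47 ± 0.35), the collagen gene COL28A1 (2.18 ± 0.20) and KMO, an enzyme of tryptophan breakdown (2.01 ± 0.34). The largest falls included SCNN1G (-3.71 ± 0.42), the semaphorin SEMA5A (-2.85 ± 0.36), INSYN2A (-2.92 ± 0.40), SYTL5 (-2.71 ± 0.35) and RAMP1 (-2.70 ± 0.37). Without vehicle replicate 4 the count fell to 1915, and with upper-quartile scaling the split moved to 1773 higher and 1424 lower.

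Between the doses in HCI-011, 1104 genes differed, 445 higher and 659 lower at 80 than at 1 mg/kg, of which 78 and 166 by at least 2-fold. MYC fell further from 20.4 ± 3.64 to 3.56 ± 1.00 CPM (-2.52 ± 0.30, adjusted p = 7.50e-05) and PDZK1 from 8.78 ± 0.546 to 0.984 ± 0.187 CPM (-3.15 ± 0.29). Estrogen-induced targets fell further in 24 of 51 cases (36 when adjusted over the list alone; score difference -0.88 ± 0.05, camera adjusted p = 4.71e-46), among them RAPGEFL1 at -1.90 ± 0.18 and IGFBP4, a binding protein of insulin-like growth factors, at -1.73 ± 0.18. Repressed targets rose further in 6 cases (11 when adjusted over the list alone; camera adjusted p = 7.21e-12), with TP53INP2 at 1.14 ± 0.15. Mitosis genes fell further in 24 of 28 cases (camera adjusted p = 5.53e-41), with AURKA at -0.61 ± 0.10 and BUB1B at -0.63 ± 0.11, and G1/S genes in 21 of 31 (camera adjusted p = 1.30e-31), with RFC3 at -0.62 ± 0.10 and MCM3 at -0.43 ± 0.08. With an estimated correlation these calls held (adjusted p = 2.34e-06, 1.37e-05, 0.0261 and 0.0270 in this order). ESR1 (0.41 ± 0.24, adjusted p = 0.402) and PGR (-0.78 ± 0.34, adjusted p = 0.232) did not differ at the threshold.

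Cholesterol genes fell further in 5 of 24 cases, with ACAT2 at -0.74 ± 0.13 (camera adjusted p = 1.35e-08; adjusted p = 0.208 with an estimated correlation). Camera also called interferon-stimulated genes lower (3 of 27 members; adjusted p = 1.89e-07, and adjusted p = 0.307 with an estimated correlation) and antigen presentation lower (1 member, 7 when adjusted over the list alone; adjusted p = 0.000438, and adjusted p = 0.355 with an estimated correlation). Ribosome biogenesis was called lower with 0 members passing (11 when adjusted over the list alone; adjusted p = 2.96e-05, and adjusted p = 0.216 with an estimated correlation), and fibroblast markers were called higher with 1 member higher and 1 lower (adjusted p = 0.000231, and adjusted p = 0.387 with an estimated correlation). Hypoxia (adjusted p = 0.0398; adjusted p = 0.658 with an estimated correlation) and cyclin genes (adjusted p = 0.0417; adjusted p = 0.202 with an estimated correlation) were called lower near the threshold. The hypoxia call ended without 1 mg/kg replicates 1, 3 or 4 (adjusted p = 0.0590, 0.338 and 0.222) or 80 mg/kg replicates 1, 2 or 4 (0.153, 0.167 and 0.179), and the cyclin call without 1 mg/kg replicates 1 or 2 (0.0690 and 0.0587) or 80 mg/kg replicates 2 or 3 (0.10 and 0.0624).

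Other genes lower at 80 than at 1 mg/kg were ERICH3 (-2.81 ± 0.44), KCNH1 (-2.62 ± 0.35) and the adrenergic receptor ADRA2A (-2.58 ± 0.34), and among those higher were CYBRD1 (2.15 ± 0.38) and COLEC12 (1.98 ± 0.32). The count moved to 518 without 1 mg/kg replicate 1, 661 without 1 mg/kg replicate 4, and 683, 524 and 678 without 80 mg/kg replicates 1, 2 and 4. It was 476 without 1 mg/kg replicate 2 and 80 mg/kg replicate 2 together, 1669 with DESeq2, 1925 in a fit of HCI-011 alone and 3438 with limma-voom, where the larger part was higher (1860 and 1578 lower). Without 1 mg/kg replicate 2 the split was 239 higher and 599 lower.

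In HCI-003, the high dose lowered estrogen targets, and ESR1 was lower rather than higher. PGR fell from 388 ± 225 to 20.2 ± 6.25 CPM (-4.26 ± 0.38, adjusted p = 2.56e-07), GREB1 from 1185 ± 280 to 50 ± 10.6 CPM (-4.57 ± 0.24, adjusted p = 1.19e-10) and TFF1 from 875 ± 489 to 65.2 ± 25.9 CPM (-3.75 ± 0.38). ESR1 fell from 437 ± 107 to 222 ± 111 CPM (-0.98 ± 0.24, adjusted p = 0.00547). In a fit of those 8 libraries alone the fall in ESR1 no longer passed (adjusted p = 0.0847). MYC fell from 120 ± 20.7 to 23.3 ± 9.20 CPM (-2.37 ± 0.28). In all 4847 genes changed, 2293 higher and 2554 lower, of which 706 rose and 520 fell at least 2-fold. With the host stroma score as a covariate the larger part was higher, 2028 against 1943 lower.

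Of the estrogen-induced targets 38 fell and 0 rose (42 and 1 when adjusted over the list alone; score difference -1.55 ± 0.08, camera adjusted p = 3.75e-56), with SUSD3 at -2.91 ± 0.20, PDZK1 at -4.07 ± 0.29 and RBBP8, a factor of DNA end resection, at -2.63 ± 0.20. Of the repressed targets 12 rose (15 when adjusted over the list alone; score difference 0.94 ± 0.07, camera adjusted p = 5.35e-12), with BLNK at 1.40 ± 0.13 and ERBB2 at 0.81 ± 0.10. Ribosome biogenesis genes fell in 17 of 20 cases (camera adjusted p = 9.17e-19), with NOP56 at -0.80 ± 0.07 and FBL at -0.92 ± 0.09. These calls held with an estimated correlation (adjusted p = 5.35e-07, 1.82e-05 and 0.00926). Mitosis genes fell in 27 of 28 cases, with AURKB at -1.08 ± 0.14 and MKI67 at -0.83 ± 0.13 (score difference -0.78 ± 0.12; camera adjusted p = 9.70e-31; adjusted p = 0.0523 with an estimated correlation). G1/S genes fell in 25 of 31 cases, with MCM2 at -0.72 ± 0.10 (camera adjusted p = 2.68e-19; adjusted p = 0.101 with an estimated correlation).

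Immediate early genes rose in 7 of 15 cases (9 when adjusted over the list alone), with NR4A1 at 0.90 ± 0.16 and ZFP36 at 0.73 ± 0.11 (camera adjusted p = 6.82e-06; adjusted p = 0.201 with an estimated correlation). Luminal genes had 8 members higher and 2 lower, with the claudin CLDN4 at 0.89 ± 0.10 and KRT7 at 1.07 ± 0.16 (camera adjusted p = 0.00958; adjusted p = 0.201 with an estimated correlation). Antigen presentation had 3 members higher, with the peptide trimming enzyme ERAP1 at 0.65 ± 0.09 (camera adjusted p = 0.00138; adjusted p = 0.420 with an estimated correlation). Fibroblast markers were called higher with 3 members rising (camera adjusted p = 0.00857; adjusted p = 0.597 with an estimated correlation), and the call ended without vehicle replicate 1 (adjusted p = 0.0534) or 80 mg/kg replicate 4 (0.0525). Host stroma scores were highest in 80 mg/kg replicates 4 and 1 (0.507 and 0.303 above the model mean, log2) and lowest in vehicle replicate 1 (-0.509). Basal genes were called higher with 2 members rising (camera adjusted p = 0.0399; adjusted p = 0.597 with an estimated correlation), and this ended without vehicle replicates 2 or 4 (0.0552 and 0.0732) or 80 mg/kg replicates 1 or 4 (0.318 and 0.0610). Mitochondrially encoded genes fell in 4 of 13 cases (camera adjusted p = 0.00796; adjusted p = 0.597 with an estimated correlation), which ended without vehicle replicate 2 (0.0571). The other lists did not pass camera. Cholesterol genes had 4 members higher and 2 lower, and p53 targets 5 higher and 1 lower. BCL2 family genes had 4 higher and 2 lower, with BMF at 1.00 ± 0.14, and hypoxia genes 0 higher and 1 lower.

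The largest falls included LINC01016 (-6.23 ± 0.54), SERPINA6, the cortisol-binding globulin (-5.84 ± 0.73), the GDNF co-receptor GFRA1 (-4.56 ± 0.41), the cytokine IL20 (-4.48 ± 0.47), the neuropeptide Y receptor NPY1R (-4.38 ± 0.66) and KCNH1 (-4.35 ± 0.36). The largest rises included the transcription factor POU4F3 (5.81 ± 0.86), GP2 (4.35 ± 0.61), the pepsinogen gene PGC (4.32 ± 0.57), MS4A7 (3.93 ± 0.36), MS4A14 (3.67 ± 0.29) and the secreted protein PIP (3.35 ± 0.49). CDKN1A rose by 0.69 ± 0.22 (adjusted p = 0.0272), which no longer passed without vehicle replicates 2 or 4 (0.0661 and 0.0767) or 80 mg/kg replicates 1 or 4 (0.0719 and 0.0973), without a filter on low counts (0.0751) or with the host stroma score as a covariate (0.160).

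At 1 mg/kg in HCI-003 estrogen targets fell. PGR fell from 388 ± 225 to 19.3 ± 5.44 CPM (-4.33 ± 0.38, adjusted p = 2.37e-07), GREB1 to 103 ± 34.3 CPM (-3.52 ± 0.22), TFF1 to 103 ± 49.2 CPM (-3.09 ± 0.37) and MYC to 37.4 ± 7.61 CPM (-1.68 ± 0.27). MKI67 fell by 0.97 ± 0.13, and ERBB2 rose by 0.81 ± 0.10 and GATA3 by 0.73 ± 0.09. CDKN1A rose by 0.84 ± 0.22 (adjusted p = 0.0105). ESR1 was lower (-0.86 ± 0.24, adjusted p = 0.0158), a call that ended without vehicle replicate 1 (0.0592), without 1 mg/kg replicate 2 (0.0595) and in a fit of HCI-003 alone (0.0909). In all 3928 genes changed, 1783 higher and 2145 lower, of which 421 rose and 474 fell at least 2-fold, and a fit of those 8 libraries alone gave 1920. Fits of each model alone gave 2644 genes here and 4351 in HCI-011 at this dose. Which model changed more genes at 1 mg/kg is therefore not settled.

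Of the estrogen-induced targets 36 fell and 1 rose, ABCA3 at 0.56 ± 0.16 (42 and 1 when adjusted over the list alone; score difference -1.43 ± 0.09, camera adjusted p = 2.86e-54), and 6 of 20 repressed targets rose (camera adjusted p = 1.57e-09), with NBEA at 1.51 ± 0.20. All 28 mitosis genes fell (score difference -0.84 ± 0.14, camera adjusted p = 6.68e-42), with HMMR at -1.04 ± 0.14, and so did 16 of 20 ribosome biogenesis genes (camera adjusted p = 3.52e-18), with GNL3 at -0.61 ± 0.07. These calls held with an estimated correlation (adjusted p = 7.82e-07, 0.000103, 0.0172 and 0.0101). G1/S genes fell in 27 of 31 cases, with MCM10 at -0.88 ± 0.15 (camera adjusted p = 9.63e-20; adjusted p = 0.0936 with an estimated correlation). Mitochondrially encoded genes fell in 10 of 13 cases (camera adjusted p = 2.62e-07; adjusted p = 0.225 with an estimated correlation). Immediate early genes rose in 5 cases (9 when adjusted over the list alone), with NR4A1 at 0.97 ± 0.16 (camera adjusted p = 1.73e-06; adjusted p = 0.169 with an estimated correlation). Luminal genes had 4 members higher and 2 lower, with CLDN4 at 0.86 ± 0.10 (camera adjusted p = 0.00612; adjusted p = 0.169 with an estimated correlation). Basal genes had 3 higher (camera adjusted p = 0.00612; adjusted p = 0.409 with an estimated correlation) and antigen presentation 3 higher (camera adjusted p = 0.00314; adjusted p = 0.409 with an estimated correlation). Interferon-stimulated genes (3 higher; camera adjusted p = 0.0354; adjusted p = 0.803 with an estimated correlation) and fibroblast markers (2 higher; camera adjusted p = 0.0183; adjusted p = 0.683 with an estimated correlation) were called higher. The interferon call ended without vehicle replicate 1 (0.425) or 1 mg/kg replicates 2 or 4 (0.104 and 0.101), and the fibroblast call without vehicle replicate 1 (0.116).

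Large falls at 1 mg/kg included SERPINA6 (-6.60 ± 0.77), LINC01016 (-4.51 ± 0.47), GFRA1 (-4.45 ± 0.41), KCNH1 (-4.23 ± 0.36) and BMPER, a secreted binder of bone morphogenetic proteins (-3.79 ± 0.45). Large rises included PGC (4.26 ± 0.57), the keratin KRT20 (3.90 ± 0.67), PIP (3.54 ± 0.49), the signalling gene WNT11 (3.53 ± 0.45), MALL (3.45 ± 0.37), the desmosomal cadherin DSC1 (3.23 ± 0.56) and MS4A7 (3.20 ± 0.35).

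**Figure D1:**
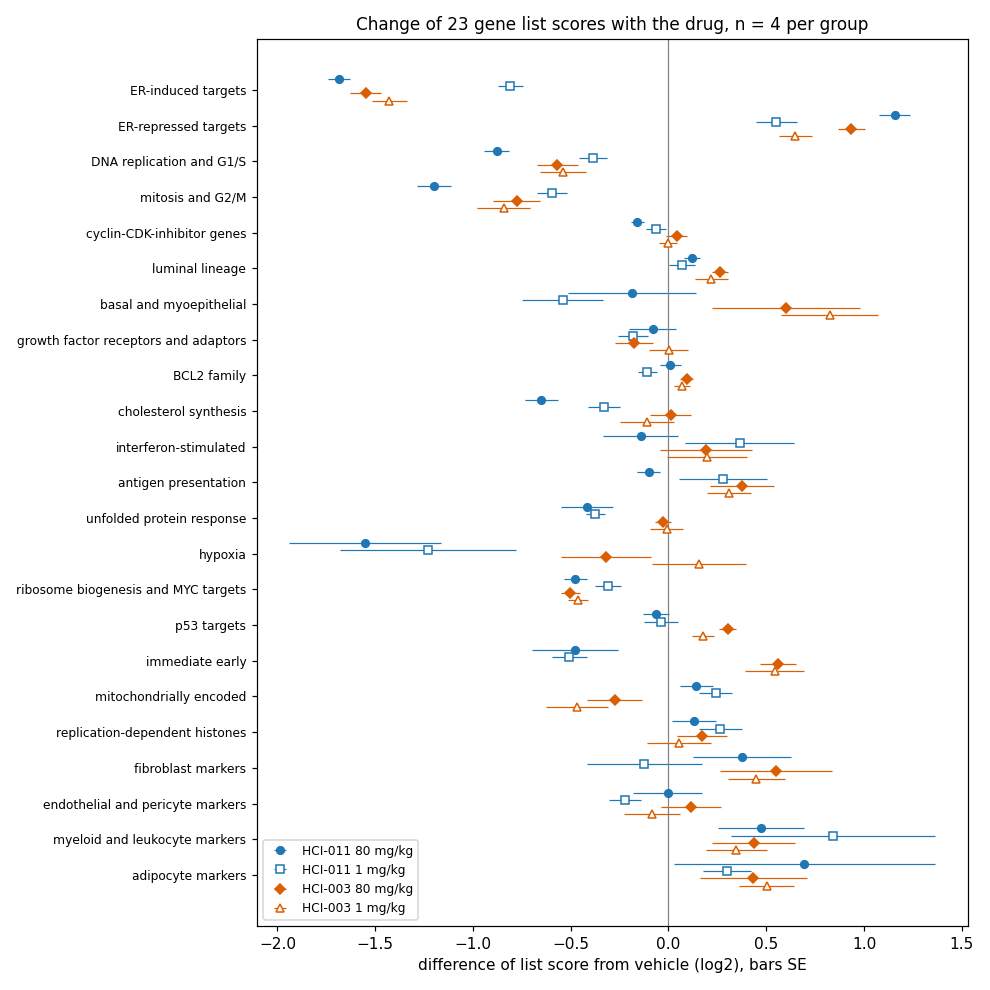
Difference in list score (mean log2 CPM over the tested members) from vehicle for 23 gene lists at 80 and 1 mg/kg in each model, as points with bars for the SE (n = 4 libraries per group). Estrogen-induced targets lie at -1.68 and -0.81 in HCI-011 and at -1.55 and -1.43 in HCI-003 for 80 and 1 mg/kg.

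Between 80 and 1 mg/kg in HCI-003, 0 genes passed the edgeR test at an adjusted p of 0.05, and the smallest adjusted p was 0.109. At an unadjusted p under 0.05 there were 2868 genes where 1215 would be expected without any difference. DESeq2 called 152 genes and limma-voom 22. GREB1 went from 103 ± 34.3 to 50 ± 10.6 CPM (-1.05 ± 0.21, adjusted p = 0.109), PGR differed by 0.07 ± 0.34 (adjusted p = 0.963) and MYC by -0.69 ± 0.27 (adjusted p = 0.322). The score of estrogen-repressed targets went from 5.26 ± 0.151 at 1 mg/kg to 5.55 ± 0.114 at 80 mg/kg (SD, n = 4), and camera did not call them. The score of estrogen-induced targets differed by -0.12 ± 0.08. Camera called this list lower (adjusted p = 0.00454; adjusted p = 0.640 with an estimated correlation), hypoxia lower (score difference -0.48 ± 0.10; adjusted p = 0.000117; adjusted p = 0.978 with an estimated correlation) and mitochondrially encoded genes higher (adjusted p = 0.00423; adjusted p = 0.978 with an estimated correlation), each with 0 members passing (1 induced target higher and 4 lower when adjusted over the list alone). The first of these calls ended without 1 mg/kg replicate 3 (0.153), and the third without 1 mg/kg replicate 1 (0.0954) or 80 mg/kg replicate 1 (0.191). The count became 223 without 80 mg/kg replicate 1 and 102 without 1 mg/kg replicate 4. It was 1 without 1 mg/kg replicate 3, for ENSG00000279312, a gene without a symbol on chromosome 6 chosen after its values were seen (1.51, adjusted p = 0.0284). Without 1 mg/kg replicate 1 and 80 mg/kg replicate 2 together it was also 1, for MS4A14, chosen after its values were seen (1.59, adjusted p = 0.0430).

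**Figure D2:**
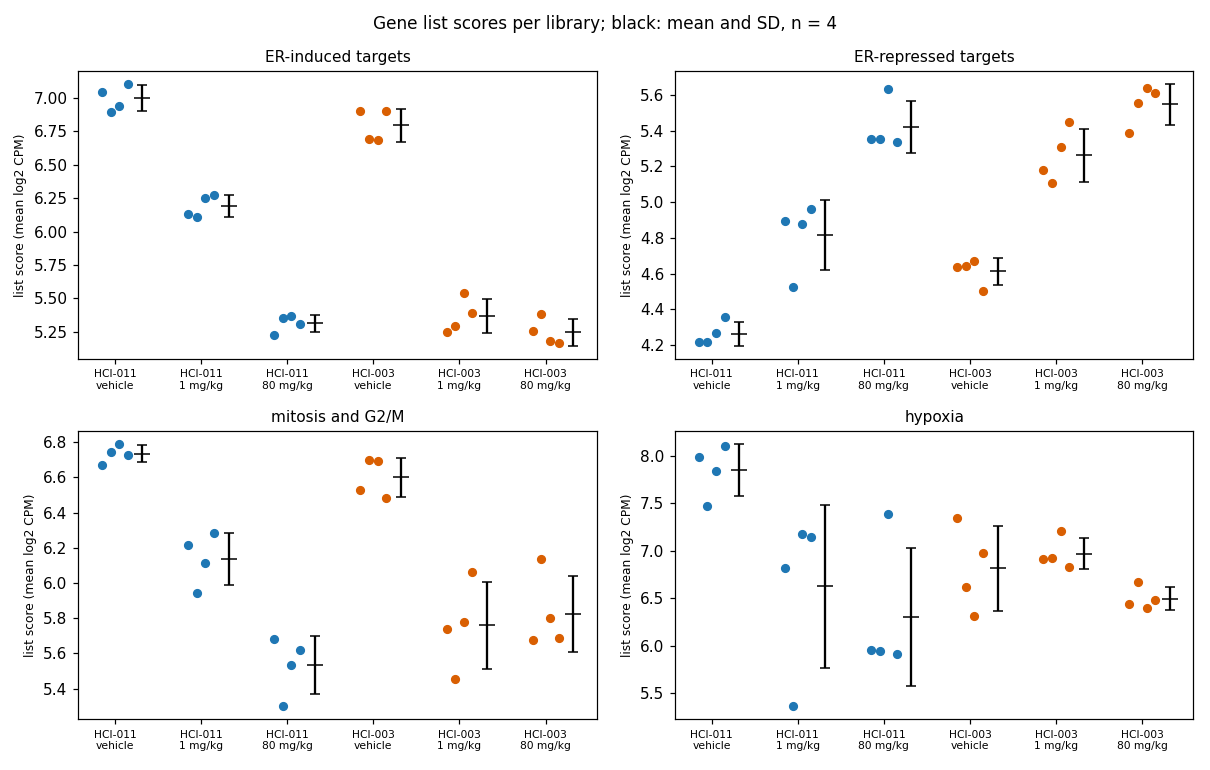
List scores per library (mean log2 CPM over the tested members, vertical axis) for estrogen-induced and estrogen-repressed targets, mitosis and hypoxia by group, with the mean and SD in black (n = 4). In HCI-011 at 80 mg/kg the hypoxia score of replicate 3 (7.39) lies above the others (5.92 to 5.96).

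Whether the high dose acted differently in the models was tested as the difference of the effects, HCI-011 minus HCI-003. ESR1 differed by 2.38 ± 0.34 (adjusted p = 0.000200), with the rise in HCI-011 and the fall in HCI-003 given above. GREB1 differed by 3.59 ± 0.30 (adjusted p = 3.22e-07), with the larger fall in HCI-003, and MYC by -1.93 ± 0.39 (adjusted p = 0.00399), with the larger fall in HCI-011. CDKN1A differed by -1.95 ± 0.32 (adjusted p = 0.000668). In all 2142 genes differed, 964 with the higher and 1178 with the lower value in HCI-011 (1211 and 1072 with upper-quartile scaling). PGR (0.81 ± 0.47, adjusted p = 0.331) and MKI67 (-0.17 ± 0.19, adjusted p = 0.661) did not pass.

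Cholesterol genes were lower in HCI-011 in this test in 16 of 24 cases (score difference -0.66 ± 0.13; camera adjusted p = 2.64e-15; adjusted p = 0.196 with an estimated correlation), with ACAT2 at -1.15 ± 0.17 and the sterol sensor INSIG1 at -1.66 ± 0.27. Immediate early genes were lower in 7 of 15 (score difference -1.04 ± 0.24; camera adjusted p = 4.71e-09; adjusted p = 0.196 with an estimated correlation), with IER3 at -1.95 ± 0.34 and KLF6 at -1.20 ± 0.23. Mitosis genes were lower in 6 of 28 (17 when adjusted over the list alone; camera adjusted p = 3.38e-08; adjusted p = 0.444 with an estimated correlation), and G1/S genes in 5 of 31 (camera adjusted p = 1.96e-05; adjusted p = 0.469 with an estimated correlation). Camera also called hypoxia (adjusted p = 2.93e-05; adjusted p = 0.444 with an estimated correlation), antigen presentation (0.000525; adjusted p = 0.444 with an estimated correlation) and the unfolded protein response (0.0110; adjusted p = 0.444 with an estimated correlation) lower in HCI-011, and mitochondrially encoded genes higher (6.62e-05; adjusted p = 0.444 with an estimated correlation). Repressed targets were called higher (0.0409; adjusted p = 0.203 with an estimated correlation) and cyclin genes lower (0.0409; adjusted p = 0.275 with an estimated correlation). The repressed target call ended without HCI-011 vehicle replicate 1 (0.0555), HCI-011 80 mg/kg replicate 3 (0.133), HCI-003 vehicle replicate 1 (0.0619) or HCI-003 80 mg/kg replicate 1 (0.0536). The cyclin call ended without HCI-011 vehicle replicate 2 (0.0676), HCI-011 80 mg/kg replicates 2 or 3 (0.0736 and 0.0720), HCI-003 vehicle replicates 2 or 4 (0.0578 and 0.0822) or HCI-003 80 mg/kg replicates 2 or 4 (0.0788 and 0.0614). Estrogen-induced targets were not called as a list (camera adjusted p = 0.552), with 8 members higher and 11 lower, among them RBBP8 at 1.67 ± 0.27 and ELOVL2 at -3.07 ± 0.49. The keratin KRT19 (-1.69 ± 0.25), CLDN4 (-0.97 ± 0.14) and BID (-0.96 ± 0.15) were lower and NXPH1 (4.83 ± 0.41) and BMPER (4.56 ± 0.70) higher in HCI-011.

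At 1 mg/kg, 740 genes differed in effect, 296 with the higher and 444 with the lower value in HCI-011. ESR1 differed by 1.86 ± 0.34 (adjusted p = 0.00491), GREB1 by 3.10 ± 0.29 (adjusted p = 7.61e-06) and TFF1 by 2.19 ± 0.48 (adjusted p = 0.0178). The TFF1 call ended without a filter on low counts (0.0501). Estrogen-induced targets were higher in HCI-011 in 14 of 51 cases (21 higher and 1 lower when adjusted over the list alone; score difference 0.62 ± 0.11; camera adjusted p = 1.06e-14), with AMZ1 at 2.28 ± 0.35 and ZNF703 at 1.14 ± 0.19, and immediate early genes lower in 8 of 15 (12 when adjusted over the list alone; camera adjusted p = 2.48e-14), with KLF6 at -1.14 ± 0.23. These calls held with an estimated correlation (adjusted p = 0.00377 and 0.0477). Mitochondrially encoded genes were higher in 9 of 13 (13 when adjusted over the list alone; camera adjusted p = 6.44e-16; adjusted p = 0.0688 with an estimated correlation). Camera called hypoxia (1.39e-09; adjusted p = 0.309 with an estimated correlation), basal genes (4.29e-05; adjusted p = 0.309 with an estimated correlation), cholesterol genes (8.54e-05; adjusted p = 0.390 with an estimated correlation), the unfolded protein response (0.000204; adjusted p = 0.309 with an estimated correlation) and fibroblast markers (0.000944; adjusted p = 0.465 with an estimated correlation) lower in HCI-011. It called mitosis (0.000172; adjusted p = 0.506 with an estimated correlation) and ribosome biogenesis (0.00300; adjusted p = 0.390 with an estimated correlation) higher.

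Camera calls at 1 mg/kg for G1/S (0.0234; adjusted p = 0.603 with an estimated correlation) and leukocyte markers (0.0256; adjusted p = 0.490 with an estimated correlation) were higher, and those for luminal genes (0.0476; adjusted p = 0.367 with an estimated correlation) and p53 targets (0.0485; adjusted p = 0.341 with an estimated correlation) lower. The G1/S call ended without HCI-011 1 mg/kg replicate 4 (0.190), HCI-003 vehicle replicates 2 or 3 (0.0948 and 0.0522) or HCI-003 1 mg/kg replicate 2 (0.337). The leukocyte call ended without HCI-011 vehicle replicates 3 or 4 (0.0557 and 0.0691), HCI-011 1 mg/kg replicate 2 (0.453) or HCI-003 1 mg/kg replicate 1 (0.0513). The luminal call ended without any of 8 libraries, HCI-011 vehicle replicates 2 or 4 (0.0835 and 0.0692), HCI-011 1 mg/kg replicates 1 or 2 (0.0658 and 0.115), HCI-003 vehicle replicates 2 or 4 (0.0868 and 0.0986) or HCI-003 1 mg/kg replicates 2 or 3 (0.0622 and 0.137). The p53 call ended without HCI-011 vehicle replicate 2 (0.189), HCI-011 1 mg/kg replicates 3 or 4 (0.0696 and 0.171), HCI-003 vehicle replicates 1, 2 or 4 (0.0603, 0.0634 and 0.0747) or HCI-003 1 mg/kg replicates 1 or 3 (0.121 and 0.0570). The count moved to 388 without HCI-011 vehicle replicate 4, 439 without HCI-011 vehicle replicate 1, 460 without HCI-011 1 mg/kg replicate 2, and 448 and 474 without HCI-003 1 mg/kg replicates 2 and 3.

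**Figure D3:**
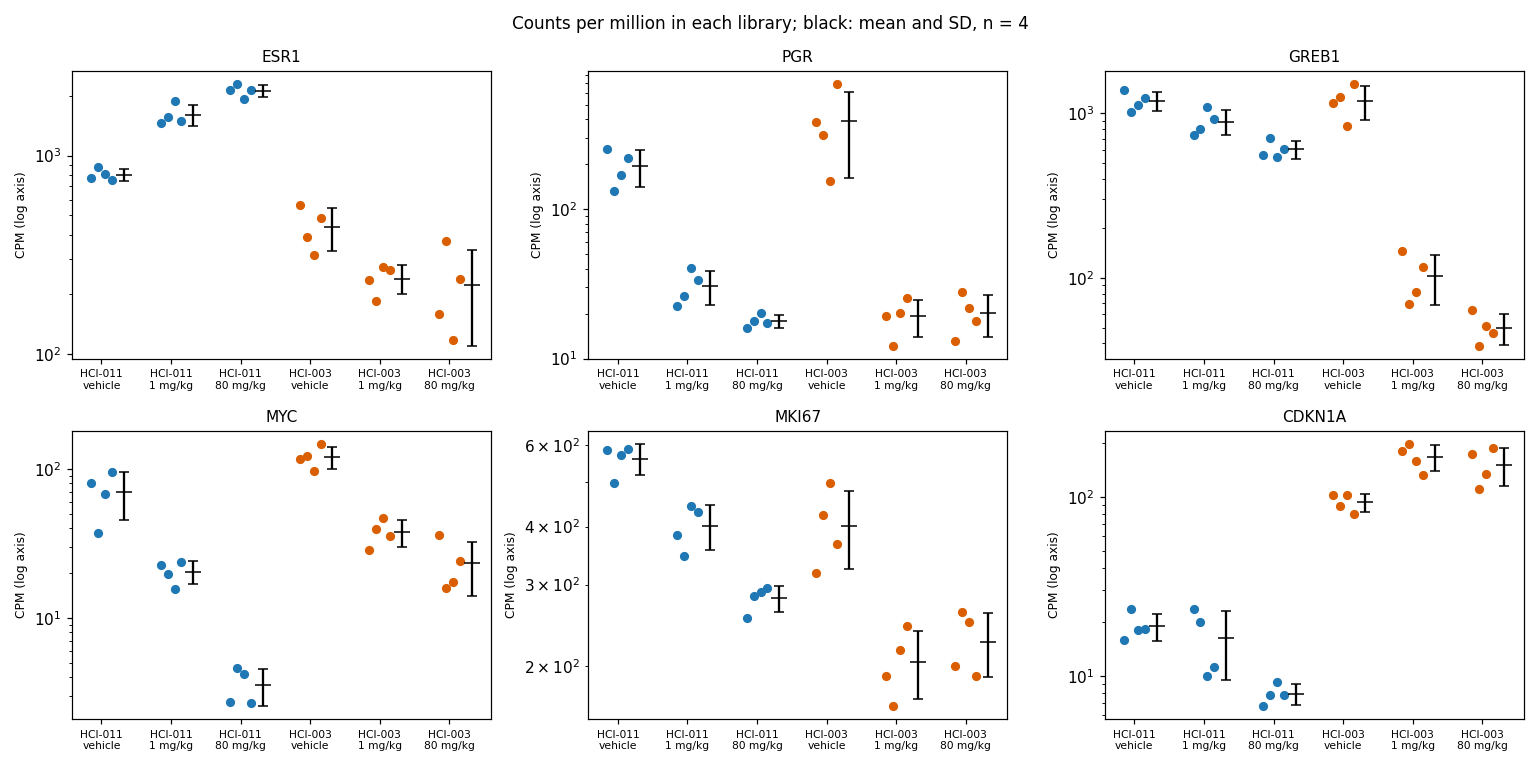
Expression of ESR1, PGR, GREB1, MYC, MKI67 and CDKN1A per library (CPM, logarithmic vertical axis) by group, with the mean and SD in black (n = 4). ESR1 rises from 800 ± 57.2 to 2121 ± 153 CPM in HCI-011 and falls from 437 ± 107 to 222 ± 111 CPM in HCI-003 from vehicle to 80 mg/kg.

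The overlap of calls asked how far the doses and the models changed the same genes. In HCI-011, 1110 genes were higher and 1682 lower at both doses, and 0 changed in opposite directions, where independence would give 196, 298 and 486. Both doses shared the vehicle libraries, so the overlap was set against other values. Simulated groups without any change against the same vehicles had almost no calls, so that their 0 shared calls say nothing about the overlap. Their covariance of effects was 0.0659, against 0.332 as measured. With the vehicle libraries split between the doses, the mean overlap over 6 splits was 381 higher, 729 lower and 0.667 opposite, with a covariance of 0.291. In HCI-003, 1190 genes were higher and 1625 lower at both doses and 0 opposite (168, 226 and 390 under independence). There the split vehicles gave 500, 838 and 5.33, with a covariance of 0.215 against 0.279 as measured and 0.0562 in the simulation. Between the models, which share no libraries, 1005 genes were higher and 1635 lower in both at 80 mg/kg, and 170 changed in opposite directions (349, 430 and 775 under independence). Of the latter, 62 including ESR1 were higher in HCI-011 and lower in HCI-003, and 108 the reverse. At 1 mg/kg, 373 were higher and 793 lower in both and 47 opposite (94.7, 156 and 244 under independence).

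Vehicle tumours of the models were compared as background for the drug effects, with 1 tumour line on each side. Interferon-stimulated genes were lower in HCI-011 in all 27 cases (score difference -5.50 ± 0.21; camera adjusted p = 1.63e-31; adjusted p = 0.0597 with an estimated correlation), with the antiviral gene IFI27 at 0.182 ± 0.0914 CPM in HCI-011 and 1268 ± 102 CPM in HCI-003 and BST2 at -2.57 ± 0.08. Antigen presentation genes were lower in 12 of 13 (camera adjusted p = 8.85e-07; adjusted p = 0.538 with an estimated correlation). Basal genes were lower in 12 and higher in 2 of 16 (camera adjusted p = 0.0218; adjusted p = 0.906 with an estimated correlation), with the integrin ITGA6 at -4.49 ± 0.22. Growth factor receptors were higher in 11 and lower in 4 of 19 (camera adjusted p = 0.0280; adjusted p = 0.731 with an estimated correlation), with FGFR3 at 5.13 ± 0.22 and FGFR2 at 6.30 ± 0.29. All 13 mitochondrially encoded genes were higher (camera adjusted p = 0.0218; adjusted p = 0.906 with an estimated correlation). ESR1 was higher in HCI-011 (0.87 ± 0.24, adjusted p = 0.00275), TFF1 also (2.09 ± 0.35), and CDKN1A (-2.30 ± 0.23) was lower, while GREB1 differed by 0.00 ± 0.20 (adjusted p = 0.993). TSPYL5 was at 283 ± 12.6 CPM in HCI-011 and 0.127 ± 0.0384 CPM in HCI-003. In all 16298 genes differed, 7666 higher and 8632 lower in HCI-011 (8160 and 8150 with upper-quartile scaling). Fibroblast (11 of 20 lower) and leukocyte markers (4 of 13 lower) were not called as lists, and for endothelial markers the median (0.27) and the score difference (-0.60 ± 0.12) had opposite signs.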

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

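The tests of ESR1, of the step between doses, of the wrong label and all splits of the libraries were chosen after the result was seen, and the test of host stroma in the hypoxia library was written before. Each list score, the total count and the CPM of the always-named genes were examined in each group for a single library far from the other 3 (Dixon's ratio above its critical value of 95% for 4 libraries), and effects were compared between models by interaction tests.

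A single library far from the others was found in 7 of 138 groups of list scores (5.07%), about as many as the 1 in 20 that chance gives, or in 7 of 222 groups (3.15%) with the total counts and single genes included. The library HCI-011 80 mg/kg replicate 3 accounted for 4 of them, with scores of 5.64 for estrogen-repressed targets (others 5.34 to 5.35), 6.15 for the unfolded protein response (5.63 to 5.66), 7.39 for hypoxia (5.92 to 5.96) and 4.80 for immediate early genes (3.89 to 4.04). The others were growth factor receptors in HCI-003 vehicle replicate 3 at 4.69 (4.86 to 4.90), the unfolded protein response in HCI-011 vehicle replicate 4 at 6.31 (6.14 to 6.16) and fibroblast markers in HCI-011 vehicle replicate 1 at 4.12 (3.57 to 3.64).

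The effect of 80 mg/kg differed between the models, as HCI-011 minus HCI-003, in 2142 genes, among them ESR1 (2.38), GREB1 (3.59), MYC (-1.93) and CDKN1A (-1.95). List scores for which camera called a difference at this dose were those of estrogen-repressed targets (0.22), G1/S (-0.31), mitosis (-0.42), cyclin genes (-0.20), cholesterol synthesis (-0.66), antigen presentation (-0.48), the unfolded protein response (-0.39), hypoxia (-1.23), immediate early genes (-1.04) and mitochondrially encoded genes (0.42). At 1 mg/kg 740 genes differed, among them ESR1 (1.86), GREB1 (3.10) and TFF1 (2.19). The lists were estrogen-induced targets (0.62), G1/S (0.15), mitosis (0.25), luminal (-0.15), basal (-1.37), cholesterol synthesis (-0.22), the unfolded protein response (-0.37), hypoxia (-1.39), ribosome biogenesis (0.15), p53 targets (-0.22), immediate early genes (-1.05), mitochondrially encoded genes (0.71), fibroblast (-0.57) and leukocyte markers (0.49). With an estimated correlation between genes, 0 of the lists at 80 mg/kg were called, and at 1 mg/kg estrogen-induced targets (adjusted p = 0.00377) and immediate early genes (0.0477).

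Other splits of the same libraries were tested for each count. In 8 of the 9 comparisons only 1 split, the real one, reached the count. With 35 splits, or 40 drawn, the smallest possible share is 1 in 35 or 1 in 40, without adjustment over the 9 comparisons. The other splits mix the groups, which adds any real difference to their spread and lowers their counts. The splits therefore do not exclude chance. In HCI-011 the real count and the highest of the other splits were 7789 and 27 for 80 mg/kg, 3058 and 8 for 1 mg/kg, and 1104 and 239 between doses. In HCI-003 they were 4847 and 619 for 80 mg/kg and 3928 and 214 for 1 mg/kg. For the differences between models they were 2142 and 0 at 80 mg/kg, 740 and 5 at 1 mg/kg, and 16298 and 0 in vehicle. Between the doses in HCI-003 the splits decide nothing about chance, since the real count was 0 and all 35 splits reach it by construction. There the highest other split gave 692 genes, with 80 mg/kg replicate 1 grouped with 1 mg/kg replicates 1, 2 and 3. That split was picked as the highest, and 9 of the other splits had calls. HCI-003 replicates also spread more than those of HCI-011, while 1 estimate of spread per gene served both models. Such calls may come from that spread, and a structure that does not follow the labelled dose stays open.

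ESR1 rose with the drug in HCI-011 and fell in HCI-003. Scaling was argued against, since the difference at 80 mg/kg was 2.38 ± 0.35 with DESeq2 size factors and 2.42 ± 0.34 with upper-quartile factors. Reads from host stroma were argued against as the whole cause, as far as the marker score shows them. The difference was 2.37 ± 0.33 with that score as a covariate. A biological difference between the tumour lines stays open as a hypothesis and was not tested apart from these libraries, since each model is 1 tumour line. The library kit of each sample is not given in the sources used here and stays open too.

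Estrogen-induced targets fell further from 1 to 80 mg/kg in HCI-011, while between these doses in HCI-003 0 genes passed the edgeR test (2868 genes at an unadjusted p under 0.05, 152 calls with DESeq2 and 22 with limma-voom). The step of the list score was -0.88 ± 0.05 in HCI-011 and -0.12 ± 0.08 in HCI-003, and the difference of -0.75 ± 0.10 lay over 2 SE from 0, which argues against a larger spread between HCI-003 libraries as the whole cause. Leaving out 1 library raised the count in HCI-003 to at most 223 (without 80 mg/kg replicate 1; 102 without 1 mg/kg replicate 4 and 1 without 1 mg/kg replicate 3), below the 518 to 1374 in HCI-011 with 1 library left out. The step of the list score then ran from -0.17 to -0.06 in HCI-003 and from -0.90 to -0.85 in HCI-011. The treated HCI-003 libraries were deeper by 5.36 M counts in the median. These values argue against 1 deviating library and against lower depth as the whole cause. They do not test an effect of 2 libraries together. The split that exchanged 80 mg/kg replicate 1 and 1 mg/kg replicate 4 of HCI-003 between the doses gave 692 genes. An exchange of these 2 libraries, or another effect of the pair, stays open. High counts were not particular to this pair. For 80 mg/kg against vehicle in HCI-003, a split that grouped 80 mg/kg replicate 1 with vehicle replicates 1, 2 and 4 gave 619 genes. A candidate explanation is that 1 mg/kg already came near the full effect on the estrogen-induced list in HCI-003 and not in HCI-011. Against a full effect on all estrogen targets, GREB1 differed between the doses in HCI-003 by -1.05 ± 0.21. The estrogen-repressed score there also went from 5.26 ± 0.151 at 1 mg/kg to 5.55 ± 0.114 at 80 mg/kg (SD, n = 4). Differing drug exposure between the models was not tested.

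The hypoxia score of HCI-011 80 mg/kg replicate 3 lay at 7.39, near the vehicle libraries (7.47 to 8.11). A vehicle library under the wrong label was argued against, as its score for estrogen-induced targets was 5.37, near the other 80 mg/kg libraries (5.23 to 5.35) and below vehicle (6.89 to 7.11). More reads from host stroma were argued against, as its centred stroma score was 0.0361, within the range of the other 3 (-0.25 to 0.58). A difference in oxygen supply between tumours, or in the time between removal and freezing, stays open and was not tested.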

How the results depend on the processing

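The fits without HCI-011 1 mg/kg replicate 2 and 80 mg/kg replicate 2, and without HCI-003 1 mg/kg replicate 1 and 80 mg/kg replicate 2, which lay farthest out on principal components 2 and 3, were chosen after the result was seen, and the other alternatives were planned. No paired analysis was possible because the animal numbers do not pair the libraries.

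Upper-quartile factors, DESeq2 size factors in the edgeR fit, the filter of 1 CPM in 12 libraries and the host stroma covariate moved none of the 9 counts of genes by more than 1.5 times. Upper-quartile factors turned the larger part from lower to higher genes in 4 comparisons, at 1 mg/kg in HCI-011 (1773 higher and 1424 lower, from 1290 and 1768), at 80 mg/kg in HCI-011 (4448 and 3650, from 3700 and 4089), in the effects that differ at 80 mg/kg (1211 and 1072, from 964 and 1178) and in vehicle (8160 and 8150, from 7666 and 8632). It turned the same way with limma-voom at 80 mg/kg (5498 and 5430) and between doses in HCI-011 (1860 and 1578, from 445 and 659), with the host stroma covariate at 80 mg/kg in HCI-003 (2028 and 1943, from 2293 and 2554) and with the test against 1.5-fold in the effects that differ at 1 mg/kg (18 and 11, from 296 and 444), so that which direction holds more genes is not settled in these comparisons. The test against a 1.5-fold change gave fewer genes by its construction, 1490 and 124 for 80 and 1 mg/kg in HCI-011 and 47 between these doses, 565 and 333 for 80 and 1 mg/kg in HCI-003, 283 and 29 for the effects that differ between models at 80 and 1 mg/kg, and 9628 for vehicle between models, and it stayed at 0 between doses in HCI-003. With limma-voom the count was 5223 at 1 mg/kg and 3438 between doses in HCI-011, 22 between doses in HCI-003, and 3537 and 1392 for the effects that differ between models at 80 and 1 mg/kg. With DESeq2 it was 1669 between doses in HCI-011, 152 between doses in HCI-003 and 1321 for the effects that differ at 1 mg/kg. The fit of 12 libraries gave 1925 between doses in HCI-011, and the fit of 8 libraries 1920 at 1 mg/kg in HCI-003. With 12 libraries the counts in HCI-011 went from 7789 to 8996 at 80 mg/kg and from 3058 to 4351 at 1 mg/kg. In HCI-003 they went from 4847 to 3631 and from 3928 to 2644, so that the order of the models at 1 mg/kg turned. Without a filter, 437 effects differed at 1 mg/kg. Without the 2 HCI-011 libraries named above, the counts were 476 between doses in HCI-011 and 441 for the effects that differ at 1 mg/kg. Without the 2 HCI-003 libraries, the count between doses in HCI-003 was 1 (MS4A14, named after its values were seen). Apart from the test against 1.5-fold, the cause was not tested.

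With each library left out in turn, counts ran from 6438 to 7296 for 80 mg/kg and from 1915 (without vehicle replicate 4) to 3056 for 1 mg/kg in HCI-011. Between doses in HCI-011 they ran from 518 (without 1 mg/kg replicate 1) to 1374, and were 661 without 1 mg/kg replicate 4 and 683, 524 and 678 without 80 mg/kg replicates 1, 2 and 4. In HCI-003 they ran from 3828 to 4604 for 80 mg/kg, from 3023 to 3803 for 1 mg/kg and from 0 to 223 (without 80 mg/kg replicate 1) between doses, with 102 without 1 mg/kg replicate 4 and 1 without 1 mg/kg replicate 3. For the effects that differ between models they ran from 1588 to 2113 at 80 mg/kg and from 388 (without HCI-011 vehicle replicate 4) to 946 at 1 mg/kg, where they were also 439 without HCI-011 vehicle replicate 1, 460 without HCI-011 1 mg/kg replicate 2, and 448 and 474 without HCI-003 1 mg/kg replicates 2 and 3. For vehicle they ran from 15609 to 16028.

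The named genes had 643 calls over the comparisons, and 12572 alternatives to them kept 11325, lost 1245 and reversed 2. Without the test against 1.5-fold, 11929 alternatives lost 890, and 501 of the 643 calls were never lost. The reversals were of CIDEC, an adipocyte lipid droplet gene, at 80 mg/kg in HCI-011, whose log2 fold change of 2.86 ± 0.89 became -0.32 (adjusted p = 0.702) without 80 mg/kg replicate 2 and -0.32 without the 2 HCI-011 libraries, and ran up to 3.27 without 80 mg/kg replicate 3, so that replicate 2 alone carried that rise. Of 88 camera calls among 207 list tests, 69 were lost and 19 held with an estimated correlation, and with fry 33 were lost, 55 held and 22 were gained. Leaving out a library kept 828 of 896 retests of these calls and lost 68, and it gained 58 of 1128 for lists not called. DESeq2 size factors changed 0 of the 207 tests, and a prior count of 0.5 moved 0 of the 207 score differences by more than the spread between replicates. For depth, 1.5-fold changes were called in about 50% of cases in the simulated data (47.8% to 55.2%), so that small changes of single genes can have been missed. These rates cover neither genes with low counts nor the larger spread between HCI-003 libraries. They may be too low where many genes changed, since the simulation changed only a small share of genes.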

Other observations

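The tests of genes near ESR1 and of p53 targets were chosen after the result was seen, as was the stroma comparison in the last paragraph. Some of the genes named by the fixed rule differed in their effect between the models, and no common theme of these genes was tested. The keratin KRT8 fell in HCI-011 at 80 mg/kg (-1.92 ± 0.21) and differed between models by -1.82 ± 0.29 (adjusted p = 0.000551). The immediate early gene NR4A1 rose in HCI-003 at both doses (0.90 ± 0.16 and 0.97 ± 0.16), and its effect in HCI-011 was lower by 1.00 ± 0.23 at 80 mg/kg (adjusted p = 0.00786). S100A7, an antimicrobial protein of squamous epithelia, fell in HCI-011 at both doses (-5.85 ± 0.84 and -4.10 ± 0.70) and differed between models at 80 mg/kg (-5.98 ± 1.02). GPM6A, a membrane glycoprotein, differed at both doses (-4.45 ± 0.87 and -4.10 ± 0.85), and AOX1, an aldehyde oxidase, at 80 mg/kg (-4.61 ± 0.83).

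A hypothesis was that genes beside ESR1 change with it, which would place part of the difference between models at the level of the region. Of the 9 tested genes within 500 kb, 5 had a difference past the edgeR threshold, namely ARMT1 (1.64 ± 0.17), RMND1 (1.75 ± 0.15), ZBTB2 (0.59 ± 0.10), RNU6-813P (2.56 ± 0.49) and HSPA8P15 (1.26 ± 0.36), and CCDC170, AKAP12, SYNE1 and a gene without a symbol did not pass. The mean difference over the 9 genes was 0.89, at percentile 99.3 of 23339 windows around other genes, which goes with the hypothesis. By position, HSPA8P15 lies within RMND1 and RNU6-813P within CCDC170, so that their values may not be separate from those of these genes. The windows overlap, and they surround genes not chosen for a large difference as ESR1 was, so that the percentile is not a p value. RMND1 rose in HCI-011 (0.40) and fell in HCI-003 (-1.35), and no other neighbour passed in HCI-011. In HCI-003 ARMT1 (-1.35), ZBTB2 (-0.52), CCDC170 (-0.65), RNU6-813P (-2.15) and HSPA8P15 (-0.85) also fell, so that the neighbours differed mainly through falls in HCI-003. A shared regulation of the region may therefore contribute. All neighbours that passed lie at lower positions than ESR1. Readthrough from ESR1 toward higher positions would reach SYNE1, which overlaps that end and differed by -0.14 ± 0.25 (adjusted p = 0.806). The values argue against such readthrough as the source of the neighbours' differences. Readthrough toward lower positions and shared reads were not tested.

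A second hypothesis was that the opposite changes of CDKN1A at 80 mg/kg go with other p53 targets. The score of the other 17 p53 targets differed between models by -0.28 ± 0.08, in the direction of CDKN1A and over 2 SE from 0. Of these targets 1 passed higher and 1 lower. The score lay over 2 SE short of a bound of -0.49, a fraction chosen from the difference of CDKN1A itself (-1.95). By model, the score of the whole list, CDKN1A included, went from 4.58 ± 0.108 in vehicle to 4.52 ± 0.0781 at 80 mg/kg in HCI-011 (SD, n = 4). In HCI-003 it went from 4.80 ± 0.0735 to 5.10 ± 0.0433. The difference therefore came mainly from a rise in HCI-003. In HCI-011, where CDKN1A fell, the list did not change beyond its spread. The values argue against a common change as large as the bound. That bound replaced an earlier test of another list whose result had been seen, so it is no independent evidence. CDKN1A in HCI-003 depends on single libraries, as given above, and a smaller p53 contribution there stays open.

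A higher share of host stroma was also examined for the rises at 80 mg/kg in HCI-003. With the stroma score as a covariate, 1778 of the 2293 genes (77.5%) were still called higher, and their median log2 fold change went from 0.67 to 0.66. The fibroblast minus endothelial score differed by 0.43 (exact two-sided p = 0.114, 4 against 4 libraries).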
